A study of Homo sapiens with 18 samples.

How the data were processed

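The deposited table of raw counts per gene was used as given. According to the labels, RNA was extracted with TRIzol, poly(A) RNA was selected with oligo(dT) beads and libraries were made with random primers. The submitters' notes name cutadapt 1.9.1, HISAT2 2.2.1, HTSeq 0.6.1, DESeq2 1.44.0 and the hg38 genome, without saying how reads were assigned to strands. The 3 rapamycin columns share 1 header name, so these libraries are called replicate A, B and C and cannot be matched to numbered samples. The table held 59251 gene symbols, of which 58212 matched the reference gene table, 19852 were at 0 in every library, and mitochondrially encoded genes had 0 counts. Genome positions come from the reference gene table (RefSeq) on GRCh38, the same build as hg38, and transcript sequences from GENCODE 29.

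Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with filterByExpr, which left 17966 genes. Library totals were scaled with TMM factors, and all 18 libraries entered 1 robust quasi-likelihood fit with 6 group means (common biological coefficient of variation 4.1%). Every p for a gene in the report is an edgeR p, adjusted by Benjamini-Hochberg over all tested genes of 1 comparison, and a gene is called at an adjusted p below 0.05. Log2 fold changes are those of the edgeR fit at its default prior count. Their standard error (SE) is approximate: the absolute log2 fold change divided by the square root of the quasi-likelihood F. A prior count of 2 was used for the log2 CPM values of the distances. Levels are counts-per-million values (CPM) with TMM factors, with the SD over 3 libraries. Distances from DMSO used genes with a mean of at least 10 CPM and a two-sided exact permutation test over the 20 arrangements of 3 against 3 libraries. The interaction of grazoprevir and split Csy4 is the log2 fold change of grazoprevir in split Csy4 cells less that in untransfected cells.

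The choices here, the gene lists and the rule for named genes were fixed before the data were examined. The 29 lists held 729 symbols, of which 714 were matched as written, 14 through an older symbol and 1 not at all. They were p53 targets, immediate early genes, interferon-stimulated genes, NF-kB targets, ATF4 targets of the integrated stress response, the endoplasmic reticulum unfolded protein response, heat shock proteins, cholesterol synthesis, fatty acid synthesis, glycolysis, hypoxia (HIF) targets, cytosolic ribosomal proteins, translation factors with 5-prime TOP mRNAs, ribosome biogenesis factors, snoRNA hosts, microRNA hosts, RNA decay and microprocessor genes, lysosome and autophagy genes, DNA replication genes, G2/M genes, replication-dependent histones, replication-independent histones, oxidative phosphorylation, mitochondrially encoded mRNAs, NRF2 targets, xenobiotic response genes, and markers of fibroblasts, blood cells and epithelial carcinoma lines. The 27 lists with at least 5 tested genes were tested with camera of limma 3.58.1 at its preset correlation of 0.01, and again with an estimated correlation, adjusted over the lists of 1 comparison. Where 1 pair of counts is given for a list, the counts adjusted over the list alone were the same. The named genes of a comparison are the 8 largest rises and 8 largest falls among called genes with a mean of at least 5 CPM in the higher group and all 3 libraries of one group above all 3 of the other. Up to 4 called members of each list with the smallest adjusted p were added, as were *FKBP1A*, *MTOR*, *ACTB* and *GAPDH* whatever their values. Unnamed loci, pseudogenes and copies that share reads were passed over.

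The alternatives were median-of-ratios factors, no filter, a filter of 1 CPM in 3 libraries, a test against a 1.2-fold change (glmTreat), DESeq2 1.42.0, a fit of only the groups compared, replicate number as a block, and leaving out each library in turn. Library-size scaling alone and a correction of each library's trend with transcript length and GC content were added after the data were seen. Counts were simulated with the mean levels, totals and dispersions of these libraries. Changes of known size between full-length Csy4 and DMSO were set only in genes with a mean of at least 1 CPM. They were recovered in 36% of genes at 1.2-fold, 74% at 1.5-fold, 94% at 2-fold and 100% at 4-fold (50 genes each), with 8 false calls among 17278 unchanged genes. Few genes were changed, which makes the adjusted threshold stricter than in a real comparison with many calls. These shares therefore do not carry over to such comparisons. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.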

Results

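Gene expression was measured by RNA sequencing of poly(A)-selected RNA from HEK-293T cells, a human embryonic kidney line that carries the large T antigen of a simian virus, a protein that binds p53. Csy4 is a bacterial CRISPR endoribonuclease that recognises a short RNA hairpin and cuts the RNA at its base. In the split form the enzyme is made in separate parts, and grazoprevir, a hepatitis C protease inhibitor, serves as the trigger that joins them. The 18 libraries fell into 6 groups of 3. Untransfected cells received DMSO (the solvent control), rapamycin (an inhibitor of the mTOR kinase, labelled 0.1 µM) or grazoprevir alone (0.5 µM). Transfected cells carried full-length Csy4 with DMSO, split Csy4 with DMSO (untriggered) or split Csy4 with grazoprevir (triggered), and their labels place the treatment 6 hours after transfection. The 3 groups with DMSO are labelled 0.5 µM, and the labels do not make clear whether this is the amount of solvent. Each label gives 70000 plated cells. Library totals were 14695997 to 19095828 counts with DMSO, 14000677 to 15415103 with rapamycin and 13711585 to 15827968 with grazoprevir. They were 12768305 to 15378381 counts with full-length Csy4, 13730138 to 16099315 with untriggered and 12362101 to 14659784 with triggered split Csy4. Of 59251 genes in the table, 17966 had enough counts to be tested, and these held 99.84% of all counts. The 10 most abundant genes took 3.4 to 4.42% of the counts of a library. The labels name no group transfected without a Csy4 construct. In every comparison of transfected with untransfected cells the transfection, the construct and the enzyme therefore differ together. They do not say whether the 3 libraries of a group came from separate cultures, so all p-values measure only the spread between these samples.

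The first question was how far each condition moved the transcriptome away from DMSO. Full-length Csy4 moved it farthest among the 5 conditions: its libraries lay 0.354 ± 0.0023 log2 units from the DMSO mean (root mean square over 10136 genes, mean ± SD, n = 3). Untriggered split Csy4 lay at 0.233 ± 0.0023, triggered split Csy4 at 0.25 ± 0.0032, rapamycin at 0.271 ± 0.0065 and grazoprevir alone at 0.123 ± 0.015. The DMSO libraries lay 0.106 ± 0.0014 from the mean of the other DMSO libraries, a background that is not measured quite like the rest, so grazoprevir and DMSO were not tested against each other by this measure. Full-length Csy4 exceeded untriggered split Csy4 by 0.121 (ratio 1.52), triggered split Csy4 by 0.104 (ratio 1.42) and rapamycin by 0.0828 (ratio 1.31). Triggered exceeded untriggered split Csy4 by 0.0167 (ratio 1.07). In each of these 4 comparisons all 3 libraries of one group lay above all 3 of the other, which gave a two-sided exact permutation p of 0.1, the smallest that 3 against 3 libraries allow, and a Benjamini-Hochberg adjusted p of 0.1. The threshold of 0.05 cannot be reached in this design.

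**Figure D1:**
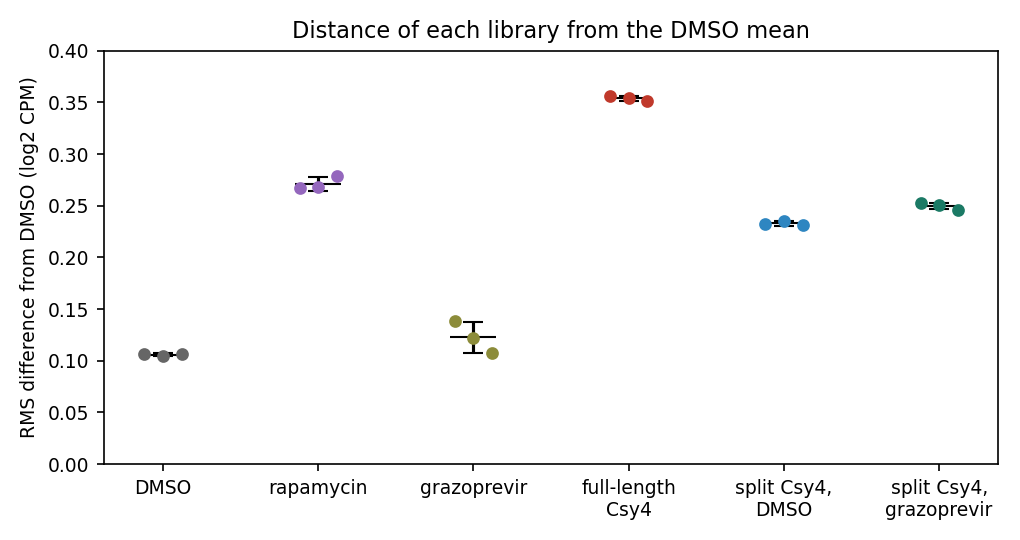
Distance of each library from the DMSO mean, as the root mean square difference in log2 CPM (vertical axis) for the 6 groups (horizontal axis). Each point is 1 library and the bars give the mean ± SD (n = 3); full-length Csy4 sits at 0.354, split Csy4 at 0.233 and 0.25, rapamycin at 0.271.

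Full-length Csy4 against DMSO asked what the complete enzyme, with its transfection, does to endogenous transcripts. *HSPA6*, a stress-inducible member of the heat shock HSP70 family, went from 0.123 ± 0.21 to 31.5 ± 2.7 CPM (mean ± SD, n = 3), on 7 counts in all DMSO libraries together. *GDF15*, a stress-induced cytokine, went from 0.228 ± 0.2 to 11.8 ± 1.7 CPM on 12 DMSO counts. *MDM2*, the ubiquitin ligase that degrades p53 and is itself a p53 target, rose by a log2 fold change of 2.06 ± 0.036 (SE). *TENM1*, a teneurin of the cell surface, fell from 266 ± 2.3 to 95.1 ± 7.1 CPM, a log2 fold change of -1.49 ± 0.051. Other large rises were *CYP4F3*, a leukotriene-oxidising cytochrome (4.68 ± 0.29), *NECTIN4*, an adhesion molecule (4.13 ± 0.27), *NHLH2*, a neuronal transcription factor (3.98 ± 0.26), and *MUC19*, a gel-forming mucin (3.82 ± 0.26). Large falls were found for *IMPA2*, an inositol monophosphatase (-1.68 ± 0.17), *HFM1*, a meiotic DNA helicase (-1.58 ± 0.18), *LHPP*, a histidine phosphatase (-1.56 ± 0.18), and *MFSD3*, a membrane transporter (-1.52 ± 0.13). On GRCh38, *HSPA6* lies on chromosome 1 from 161524540 to 161526894, *GDF15* on chromosome 19 from 18386158 to 18389176, *MDM2* on chromosome 12 from 68808172 to 68850686 and *TENM1* on chromosome X from 124375903 to 125204312. *HSPA6* resembles a neighbouring pseudogene in sequence, so some of its reads may belong to that copy.

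Of the 23 measured p53 targets, 21 rose and 1 fell with full-length Csy4, at a list median of 1.10. *TP53INP1*, a p53-induced promoter of cell death, rose by 1.93 ± 0.064, *AEN*, an apoptotic nuclease, by 1.68 ± 0.045, and *DDB2*, a DNA damage sensor, by 1.38 ± 0.059. Among 21 immediate early genes 16 rose and 2 fell (17 and 2 adjusted over the list alone), with *FOSL1* at 1.67 ± 0.17, *BTG2* at 1.57 ± 0.058 and *ATF3* at 1.37 ± 0.057, while *MYC* fell by 0.85 ± 0.042. Cholesterol synthesis genes went the other way: 18 of 24 fell and 1 rose, among them *INSIG1*, the sterol-sensing retention factor (-1.23 ± 0.049), and *SQLE*, squalene epoxidase (-0.60 ± 0.042). Of 10 fatty acid synthesis genes 9 fell, including the desaturase *SCD* (-0.57 ± 0.028), and of 20 glycolysis genes 14 fell, including *GAPDH* (-0.50 ± 0.028). Hypoxia targets fell in 8 of 12 cases and rose in 1 (9 and 2 adjusted over the list alone), with the collagen-modifying *P4HA1* at -0.64 ± 0.046. Of 30 ATF4 targets 16 fell and 6 rose, with the serine synthesis genes *PHGDH* at -0.71 ± 0.04 and *PSAT1* at -0.63 ± 0.035. The median of that list was -0.20, while its mean, which *GDF15* enters at 5.57, was 0.08. Of 15 translation factors with 5-prime TOP mRNAs 14 fell and 1 rose, with *NAP1L1* at -0.64 ± 0.034. In the replication-dependent histone list 13 of 22 rose and 1 fell, with *H3C6* at 3.09 ± 0.28, although histone mRNAs lack poly(A) tails and near-identical copies share reads. These 9 lists were called by camera both with its preset and with an estimated correlation (adjusted p = 2.07e-05 for p53 targets and 0.0403 or less for the other 8).

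A further 4 lists were called only with the preset correlation. Cytosolic ribosomal protein genes fell in 70 of 79 cases with none rising, with *RPL3* at -0.66 ± 0.028 and *RPLP0* at -0.60 ± 0.028 (adjusted p = 0.105 with an estimated correlation). Nuclear-encoded oxidative phosphorylation genes fell in 48 of 66 (49 adjusted over the list alone), with *UQCRC1* at -0.63 ± 0.047 (adjusted p = 0.089 with an estimated correlation). DNA replication genes fell in 19 of 30 and rose in 3 (20 and 3 adjusted over the list alone), with the polymerase subunit *POLA1* at -0.62 ± 0.042 (adjusted p = 0.0644 with an estimated correlation). Among 18 snoRNA host genes 10 rose and 3 fell, with *SNHG17* at 1.14 ± 0.088 (adjusted p = 0.224 with an estimated correlation). The other lists were not called. Members rose and fell, in this order, as 8 and 5 of 19 for heat shock proteins, 6 and 5 of 19 for the unfolded protein response, 11 and 3 of 26 for G2/M genes and 12 and 8 of 28 for lysosome genes. They did so as 8 and 8 of 27 for ribosome biogenesis, 11 and 11 of 36 for RNA decay and microprocessor genes, 5 and 5 of 14 for NRF2 targets and 4 and 4 of 29 for interferon-stimulated genes. For NF-kB targets the counts were 1 and 2 of 13, for microRNA hosts 1 and 2 of 9, for replication-independent histones 2 and 4 of 10 and for xenobiotic response genes 2 and 2 of 6. Camera did not call the markers of other cell types: 1 rose and 4 fell of 6 fibroblast markers, at a median of -0.84 (adjusted p = 0.371), and 1 rose and 1 fell of 6 epithelial carcinoma line markers (adjusted p = 0.868). Of the 3 measured blood markers, too few to test, 1 rose and 1 fell. No counts fell on the mitochondrially encoded mRNAs. Adjusted over the list alone, rises and falls became 9 and 5 for heat shock proteins, 13 and 8 for lysosome genes, 3 and 4 for interferon-stimulated genes, 1 and 4 for microRNA hosts and 0 and 2 for NF-kB targets.

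In all, 8425 of the 17966 genes differed at an adjusted p below 0.05 (46.9%, 4110 higher and 4315 lower), 869 rose and 275 fell at least 2-fold, and 69.3% of the called genes changed by less than 1.5-fold. The groups did not overlap in 54% of genes, against 10% by chance. The balance of rises and falls moved with the processing: 48.8% of calls were higher with TMM factors, 50.5% with median-of-ratios factors, 61.1% with library-size scaling alone and 52% with the length and GC correction (47.2% in the same genes uncorrected). Genes named in advance whatever their values moved too. The housekeeping gene *ACTB* rose by 0.31 ± 0.029, a call lost against a 1.2-fold threshold, and the rapamycin-binding *FKBP1A* fell by 0.35 ± 0.034. *MTOR* was at -0.13 ± 0.043, and its call ended with library-size scaling, against a 1.2-fold change and without DMSO replicate 1, wtCsy4 replicate 2 and wtCsy4 replicate 3 (highest adjusted p over the alternatives 1).

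Untriggered split Csy4 against DMSO measured the background of the split system. *CMYA5*, a muscle scaffold protein, rose from 3.58 ± 0.2 to 13.6 ± 0.79 CPM (n = 3), a log2 fold change of 1.93 ± 0.15. *AMH*, anti-Müllerian hormone, rose by 1.70 ± 0.13 and *DRP2*, a dystrophin relative, by 1.31 ± 0.16. *ABHD14B*, a serine hydrolase, fell from 47.5 ± 3.6 to 18.7 ± 0.95 CPM, a log2 fold change of -1.34 ± 0.079. *HFM1* fell by 1.56 ± 0.18, *RAB26*, a vesicle GTPase, by 1.61 ± 0.24, and *LGALS3BP*, a secreted galectin-binding protein, by 1.19 ± 0.12. *CCDC183* and its antisense RNA *CCDC183-AS1* rose by 1.97 ± 0.23 and 1.66 ± 0.15, but they overlap, and without a stated strand setting their reads cannot be assigned with certainty. *CMYA5* lies on chromosome 5 from 79689836 to 79800222, *AMH* on chromosome 19 from 2249323 to 2252073 and *ABHD14B* on chromosome 3 from 51968510 to 51974630.

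Of the 23 p53 targets 11 rose and 1 fell, at a list median of 0.16, with *AEN* at 0.50 ± 0.047, *BAX* at 0.44 ± 0.06 and *MDM2* at 0.35 ± 0.036 (list adjusted p = 0.1 with an estimated correlation). Immediate early genes rose in 11 of 21 cases and fell in 1 (14 and 1 adjusted over the list alone), with *ATF3* at 0.50 ± 0.06 and *MYC* at -0.49 ± 0.041 (adjusted p = 0.1 with an estimated correlation). Hypoxia targets fell in 7 of 12 and rose in 1 (8 and 1 adjusted over the list alone), and ATF4 targets fell in 13 of 30 and rose in 6 (14 and 6 adjusted over the list alone), with the mitochondrial serine enzyme *SHMT2* at -0.61 ± 0.041 (adjusted p = 0.1 with an estimated correlation for both lists). The ATF4 list had a median of -0.12 and a mean of 0.01. DNA replication genes fell in 15 of 30 and rose in 1, glycolysis genes fell in 10 of 20 and rose in 1, and cholesterol synthesis genes rose in 9 of 24 and fell in 4 (10 and 5 adjusted over the list alone), each with an adjusted p of 0.116 with an estimated correlation. Ribosomal protein genes fell in 20 of 79 and rose in 2, at a median of -0.05 (adjusted p = 0.565 with an estimated correlation). Single members with larger changes were *HMOX1*, heme oxygenase (0.92 ± 0.09), *BAG3*, a chaperone partner (0.67 ± 0.065), *SNHG1*, a snoRNA host (0.69 ± 0.035), and *TOP2A*, a topoisomerase (-0.51 ± 0.031). Camera called 14 of the 27 tested lists with the preset correlation and 0 with an estimated one. edgeR called 5185 genes (28.9%, 2650 higher and 2535 lower), of which 310 rose and 117 fell at least 2-fold and 82% changed by less than 1.5-fold. In 40.6% of genes the groups did not overlap, against 10% by chance. The *MDM2* call was lost when tested against a 1.2-fold change, as were those of *GAPDH* (-0.20 ± 0.028), *FKBP1A* (-0.31 ± 0.034) and *MTOR* (-0.19 ± 0.043), while *ACTB* rose by 0.42 ± 0.029.

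Triggered split Csy4 against DMSO took in the split system with its trigger, and whether its parts joined was not measured. *ANKRD1*, a stretch-responsive transcriptional regulator, rose from 7.12 ± 0.51 to 25.7 ± 0.46 CPM (n = 3), a log2 fold change of 1.86 ± 0.11. *AMH* rose by 1.98 ± 0.13, *CMYA5* by 1.96 ± 0.15, *DNAH17*, an axonemal dynein heavy chain, by 1.80 ± 0.19 and *DUSP8*, a MAP kinase phosphatase, by 1.63 ± 0.15. *ABHD14B* fell by 1.32 ± 0.08, *MFSD3* by 1.41 ± 0.13, *HFM1* by 1.49 ± 0.18 and *RDM1*, a DNA repair protein, by 1.41 ± 0.15. Among the 23 p53 targets 15 rose and 1 fell (17 and 2 adjusted over the list alone), at a median of 0.28, with *PHLDA3* at 0.91 ± 0.11, *TP53INP1* at 0.71 ± 0.07, *AEN* at 0.66 ± 0.047 and *MDM2* at 0.60 ± 0.036. Immediate early genes rose in 11 of 21 cases and fell in 1 (13 and 1 adjusted over the list alone), with *FOSL1* at 1.46 ± 0.18 and *ATF3* at 0.93 ± 0.058. These 2 lists were called with both correlations (adjusted p = 0.0051 and 0.0107 with an estimated correlation). Ribosomal protein genes fell in 44 of 79 with none rising (48 and 1 adjusted over the list alone), with *RPLP0* at -0.46 ± 0.028 and *RPS3* at -0.39 ± 0.03 (adjusted p = 0.262 with an estimated correlation). DNA replication genes fell in 17 of 30 and rose in 1 (adjusted p = 0.11 with an estimated correlation), and TOP mRNAs fell in 11 of 15 and rose in 1 (12 and 1 adjusted over the list alone, adjusted p = 0.127 with an estimated correlation). Camera called 12 of the 27 lists, 2 of them with an estimated correlation. edgeR called 5677 genes (31.6%, 2868 higher and 2809 lower), of which 349 rose and 150 fell at least 2-fold and 80.3% changed by less than 1.5-fold. Libraries separated by group in 43.3% of genes, against 10% by chance. *ACTB* rose by 0.40 ± 0.029 and *FKBP1A* fell by 0.39 ± 0.034, while the calls of *GAPDH* (-0.24 ± 0.028) and *MTOR* (-0.21 ± 0.043) were lost against a 1.2-fold change.

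Triggered split Csy4 against grazoprevir alone held the drug constant, while the transfection, the construct and the enzyme differed together. *DNAH17* rose from 1.62 ± 0.21 to 7.48 ± 0.23 CPM (n = 3), a log2 fold change of 2.2 ± 0.2. *AMH* rose by 2.03 ± 0.13, *ANKRD1* by 1.83 ± 0.11 and *DUSP8* by 1.82 ± 0.15, and *PLEKHJ1* fell by 1.13 ± 0.096. Of the 23 p53 targets 18 rose and 3 fell, at a median of 0.28, with *TP53INP1* at 0.92 ± 0.073, and of 21 immediate early genes 10 rose and 1 fell (11 and 1 adjusted over the list alone), with *DUSP1* at 0.89 ± 0.11. These 2 lists were also called with an estimated correlation (adjusted p = 0.00915 and 0.0358). Ribosomal protein genes fell in 73 of 79 with none rising, at a median of -0.20, and oxidative phosphorylation genes fell in 47 of 66 (51 adjusted over the list alone), at a median of -0.18 (adjusted p = 0.0714 with an estimated correlation for both lists). Part of the ribosomal difference lies in the reference, since the list's median was 0.08 with grazoprevir alone and -0.12 with triggered split Csy4 against DMSO, where 44 fell. Log2 fold changes in this comparison also went with transcript length across 14998 genes, which are not independent replicates (Spearman 0.16), and this trend was not separated from the list's shift. Camera called 13 of the 27 lists, 2 of them with an estimated correlation. edgeR called 5775 genes (32.1%, 2906 higher and 2869 lower), of which 337 rose and 133 fell at least 2-fold. The groups did not overlap in 40.8% of genes, against 10% by chance.

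Full-length against split Csy4 compared transfected groups with each other. *HSPA6* was at 31.5 ± 2.7 CPM with full-length, 1.91 ± 0.5 with untriggered and 0.472 ± 0.085 with triggered split Csy4 (n = 3 each), and rose by a log2 fold change of 4.02 ± 0.2 against the untriggered form. *DHRS2*, a short-chain dehydrogenase, rose by 3.28 ± 0.24 against the untriggered and 2.39 ± 0.22 against the triggered form, and *GDF15* by 2.54 ± 0.22 and 2.53 ± 0.23. *MAP4*, a microtubule-binding protein, fell from 324 ± 10 CPM in untriggered cells to 141 ± 2.8 CPM, a log2 fold change of -1.20 ± 0.039, and by 1.16 ± 0.039 against triggered cells. *DMAC2*, an assembly factor of respiratory complex I, fell by 1.36 ± 0.077 and 1.25 ± 0.078, and *CHP1*, a calcium-binding regulator, by 1.09 ± 0.066 and 1.08 ± 0.067. The circadian kinase *CSNK1D* fell by 1.14 ± 0.047 against triggered cells. *MAP4* lies on chromosome 3 from 47850695 to 48088848 and *DHRS2* on chromosome 14 from 23630115 to 23645639.

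Among the 23 p53 targets 21 rose and 1 fell against untriggered split Csy4, at a median of 1.00, and 20 rose and 1 fell against triggered split Csy4, at a median of 0.75. *MDM2* rose by 1.71 ± 0.035 and 1.45 ± 0.035, *DDB2* by 1.5 ± 0.061 and 1.31 ± 0.06, and *TP53INP1* by 1.69 ± 0.064 and 1.23 ± 0.062. Cholesterol synthesis genes fell in 19 of 24 and rose in 1 against untriggered (20 and 1 adjusted over the list alone) and fell in 18 and rose in 1 against triggered cells (19 and 1 adjusted over the list alone). *INSIG1* was lower by 0.99 ± 0.05 and 0.92 ± 0.05, and *HMGCS1*, an early enzyme of the pathway, by 0.76 ± 0.045 and 0.66 ± 0.045. Fatty acid synthesis genes fell in 7 of 10 in both comparisons, with *SCD* at -0.51 ± 0.028 and -0.48 ± 0.028. TOP mRNAs fell in 14 and 13 of 15. Replication-dependent histone genes rose in 14 of 22 against untriggered (16 adjusted over the list alone) and in 7, with 1 falling, against triggered cells (9 and 1 adjusted over the list alone). These 5 lists were called with both correlations in both comparisons (adjusted p = 0.0427 or less with an estimated correlation). Immediate early genes rose in 7 of 21 and fell in 1 against untriggered cells (9 and 2 adjusted over the list alone, adjusted p = 0.0258 with an estimated correlation), with *BTG2* at 1.33 ± 0.058, and rose in 5 and fell in 1 against triggered cells (adjusted p = 0.0643 with an estimated correlation). Interferon-stimulated genes rose in 7 of 29 against triggered cells (10 adjusted over the list alone, adjusted p = 0.0427 with an estimated correlation), with *ISG15* at 0.71 ± 0.19 and *OASL* at 0.69 ± 0.19, calls lost against a 1.2-fold change. This list was not called with full-length Csy4 against DMSO. *OASL* was at 5.14 ± 0.24 CPM with DMSO, 5.4 ± 0.37 with full-length and 3.3 ± 0.75 with triggered split Csy4. *ISG15* was at 3.96 ± 0.54, 5.21 ± 0.32 and 3.19 ± 0.4 CPM in that order. For both genes, part of the difference lies in the lower level of triggered cells. Ribosomal protein genes fell in 69 of 79 against untriggered (73 adjusted over the list alone) and 55 against triggered cells (62 adjusted over the list alone), with *RPL32* at -0.63 ± 0.036 and -0.57 ± 0.036 (adjusted p = 0.0712 and 0.134 with an estimated correlation). Camera called 12 lists against untriggered and 13 against triggered cells, 6 and 7 of them with an estimated correlation.

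Against untriggered split Csy4, edgeR called 5024 genes (28%, 2345 higher and 2679 lower), of which 362 rose and 54 fell at least 2-fold. Against triggered split Csy4 it called 4008 genes (22.3%, 1823 higher and 2185 lower), of which 287 rose and 55 fell at least 2-fold. In 39.3% and 35.6% of genes the groups did not overlap, against 10% by chance. Whether falls outnumbered rises depended on the processing: the shares of higher calls, 46.7% and 45.5%, became 67.8% and 67.5% with library-size scaling alone. With the length and GC correction they were 51.4% and 51.7%, against 45.1% and 43.8% in the same genes uncorrected. *GAPDH* fell by 0.30 ± 0.028 and 0.26 ± 0.028, calls lost against a 1.2-fold change.

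**Figure D2:**
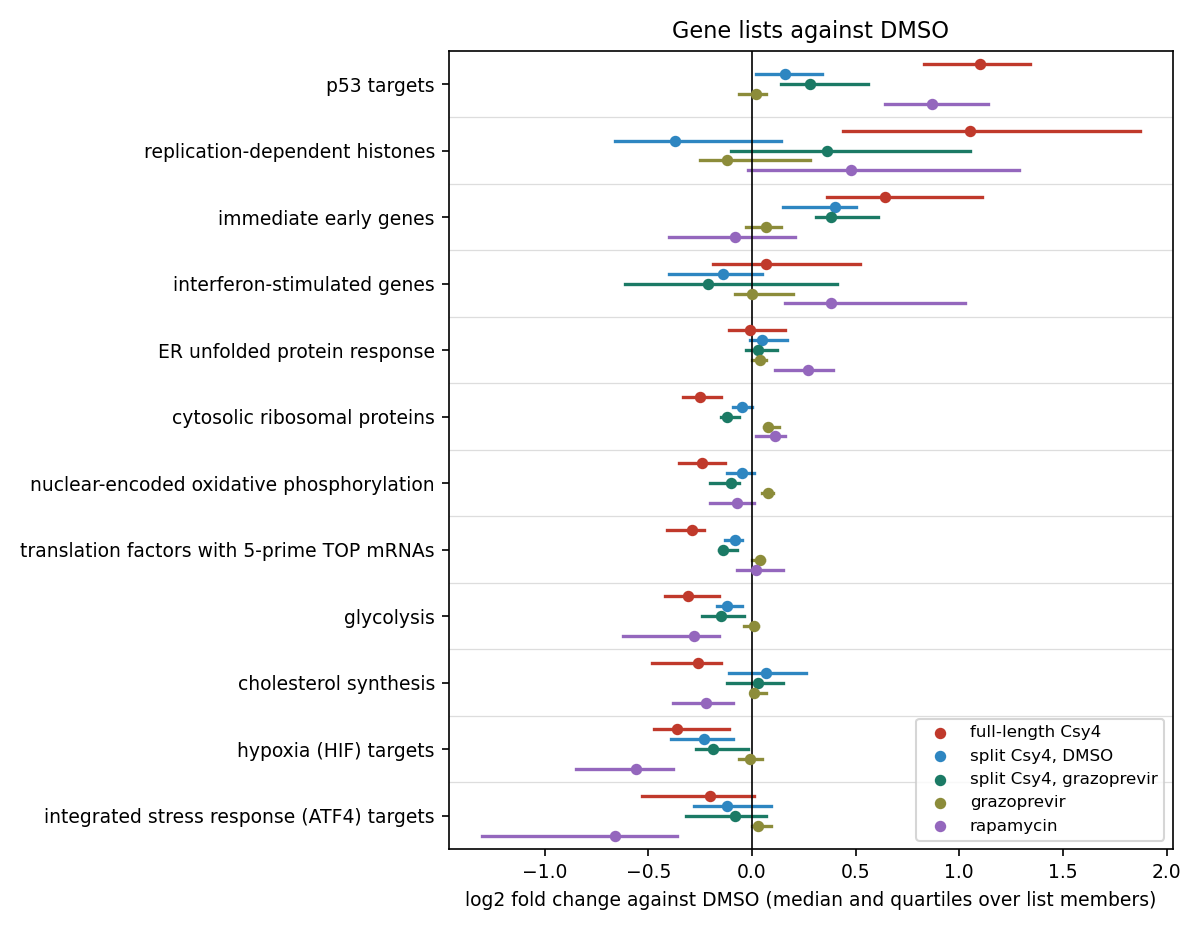
Median log2 fold change against DMSO (horizontal axis) of 12 fixed gene lists (vertical axis) in the 5 other groups, with lines for the quartiles over list members. With full-length Csy4 the p53 targets sit at 1.10 and the cytosolic ribosomal protein genes at -0.25; with rapamycin the p53 targets sit at 0.87 and the ATF4 targets at -0.66.

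Adding grazoprevir to cells with split Csy4 tested the trigger itself. *DNAH17* rose from 2.4 ± 0.39 to 7.48 ± 0.23 CPM (n = 3), a log2 fold change of 1.63 ± 0.19. *DUSP8* rose by 0.88 ± 0.14, *ANKRD1* by 0.71 ± 0.098 and *FILIP1L*, a filamin-interacting protein, by 1.11 ± 0.21. *DNAH17* lies on chromosome 17 from 78423697 to 78577396 and overlaps an antisense RNA, so some of its reads are of uncertain origin, and *DUSP8* lies on chromosome 11 from 1554051 to 1572848. Of the 23 p53 targets 4 rose and none fell (9 and 0 adjusted over the list alone), at a median of 0.14, among them *TP53INP1* (0.46 ± 0.07), *CDKN1A*, the p21 cell cycle inhibitor (0.41 ± 0.065), and *MDM2* (0.25 ± 0.036). Immediate early genes rose in 4 of 21 (6 adjusted over the list alone), with *ATF3* at 0.43 ± 0.057, and 1 of 26 G2/M genes rose (3 adjusted over the list alone). No replication-dependent histone gene was called, or 3 higher adjusted over the list alone, at a list median of 0.62, and no unfolded protein response gene was called, or 2 lower adjusted over the list alone, at a median of -0.05. These 5 lists were called with both correlations (adjusted p = 0.000408 for p53 targets and 0.049 or less for the others with an estimated correlation). A further 6 lists with no called gene were called lower with the preset correlation, among them ribosomal protein genes at a median of -0.06 and oxidative phosphorylation genes at -0.07 (adjusted p = 0.147 with an estimated correlation for both). edgeR called 36 genes, 35 higher and 1 lower, of which 5 rose and 1 fell at least 2-fold, and 1400 genes had an unadjusted p below 0.05. In a fit of these 6 libraries alone the real split called 48 genes, and the split of SplitCsy4_DMSO replicate 1 with SplitCsy4_Grazoprevir replicates 1 and 2 from the other 3 called 58. Libraries separated by group in 13.3% of genes, against 10% by chance. Without SplitCsy4_DMSO replicate 2 the count fell to 22 and without SplitCsy4_DMSO replicate 3 to 23, and without SplitCsy4_DMSO replicate 1 *FILIP1L* lost its call (adjusted p = 0.0699, within a range of 0.000185 to 0.0699 over the alternatives). The calls of *TP53INP1*, *CDKN1A*, *MDM2* and *ATF3* were lost against a 1.2-fold change. *FKBP1A* (-0.08 ± 0.034), *MTOR* (-0.02 ± 0.044), *ACTB* (-0.02 ± 0.029) and *GAPDH* (-0.04 ± 0.028) were not called.

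Grazoprevir alone against DMSO tested the trigger without Csy4, and its changes were small. *RPS29*, a protein of the small ribosomal subunit, rose from 116 ± 0.19 to 137 ± 11 CPM (n = 3), a log2 fold change of 0.25 ± 0.047. *RPS27A* rose by 0.19 ± 0.035 and *RPLP1*, a ribosomal stalk protein, by 0.18 ± 0.034. *MYDGF*, a secreted growth factor, rose by 0.34 ± 0.068 and *CNIH4*, a cargo receptor of the secretory path, by 0.27 ± 0.056. *HELZ*, an RNA helicase, and *TAOK1*, a stress kinase, fell by 0.22 ± 0.041 and 0.22 ± 0.044, and *UTRN*, utrophin, by 0.22 ± 0.046. Of 79 ribosomal protein genes 10 rose and none fell (42 and 0 adjusted over the list alone), at a median of 0.08 (adjusted p = 0.147 with an estimated correlation). Oxidative phosphorylation genes had a median of 0.08 and no called member (adjusted p = 0.163 with an estimated correlation), and snoRNA hosts a median of 0.12 with no called member, or 4 higher adjusted over the list alone (adjusted p = 0.128 with an estimated correlation). Among the 23 p53 targets none was called, at a median of 0.02. Camera called 8 of the 27 lists, all higher, with the preset correlation and 0 with an estimated one. edgeR called 36 genes (0.2%, 19 higher and 17 lower), DESeq2 99, and 1526 genes had an unadjusted p below 0.05 in edgeR. The balance moved with the processing, to 14 higher and 37 lower with no filter and 32 and 22 with library-size scaling alone. None of the edgeR calls reached 2-fold in either direction. The groups did not overlap in 13.4% of genes, against 10% by chance. The count moved with single libraries, to 3 without DMSO replicate 1, 10 without DMSO replicate 2, 11 without DMSO replicate 3, 112 without Grazoprevir replicate 1, 5 without Grazoprevir replicate 2 and 17 without Grazoprevir replicate 3, and every gene named here lost its call without at least 1 of them (highest adjusted p over the alternatives 1). *FKBP1A* (0.01 ± 0.033), *MTOR* (-0.14 ± 0.043), *ACTB* (0.05 ± 0.029) and *GAPDH* (0.03 ± 0.028) were not called.

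Rapamycin against DMSO gave the profile of a known drug in the same cells. *SLC7A11*, the cystine transporter, fell from 73.3 ± 1.2 to 8.82 ± 0.54 CPM (n = 3), a log2 fold change of -3.05 ± 0.084. *DDIT4*, a stress-induced inhibitor of mTOR signalling, fell by 2.03 ± 0.065, *ETV4*, an ETS transcription factor, by 2.90 ± 0.19 and *ALDH1L2*, a mitochondrial folate enzyme, by 1.96 ± 0.068. *INPP5D*, an inositol phosphatase of blood cells, rose from 2.87 ± 0.43 to 23.3 ± 3 CPM, a log2 fold change of 3.02 ± 0.15, and *ACTA2*, smooth muscle actin, rose by 2.37 ± 0.14. *MDM2* rose by 1.80 ± 0.036 and *CDKN1A* by 1.46 ± 0.059. *SLC7A11* lies on chromosome 4 from 138164097 to 138242349, *INPP5D* on chromosome 2 from 233060342 to 233207903 and *CDKN1A* on chromosome 6 from 36676463 to 36687332. Of the 30 ATF4 targets 25 fell and 2 rose (26 and 2 adjusted over the list alone), at a median of -0.66, with *PSAT1* at -1.22 ± 0.036 and *ATF4* itself at -0.94 ± 0.033. Of the 23 p53 targets 22 rose and none fell, at a median of 0.87, with *TP53INP1* at 1.28 ± 0.067 and *EDA2R* at 1.14 ± 0.06. Hypoxia targets fell in 10 of 12 (11 adjusted over the list alone), with *VEGFA* at -0.67 ± 0.063, and glycolysis genes fell in 16 of 20 and rose in 1 (17 and 1 adjusted over the list alone), with *HK2*, hexokinase, at -0.92 ± 0.057. Ribosome biogenesis factors fell in 20 of 27 and rose in 1, with *GNL3* at -0.53 ± 0.034, and cholesterol synthesis genes fell in 14 of 24 and rose in 1, with *INSIG1* at -1.45 ± 0.05. Unfolded protein response genes rose in 15 of 19 and fell in 2, with *CALR*, calreticulin, at 0.52 ± 0.03, and interferon-stimulated genes rose in 14 of 29 and fell in 2, with *IFIT2* at 1.03 ± 0.069. NRF2 targets fell in 8 of 14 and rose in 2, with *HMOX1* at -1.12 ± 0.11, and fatty acid synthesis genes fell in 6 of 10 and rose in 1, with *SCD* at -0.82 ± 0.028. These 10 lists were called with both correlations (adjusted p = 0.0486 or less with an estimated correlation). Ribosomal protein genes rose in 42 of 79 and fell in 2 (44 and 3 adjusted over the list alone), with *RPS19* at 0.39 ± 0.035 (adjusted p = 0.417 with an estimated correlation), and heat shock proteins fell in 11 of 19 and rose in 3 (adjusted p = 0.06 with an estimated correlation). Of 6 fibroblast markers 2 rose, *ACTA2* among them, and 3 fell, and 1 of 3 blood markers fell. Camera called 17 of the 27 lists, 10 of them with an estimated correlation. edgeR called 5963 genes (33.2%, 3084 higher and 2879 lower), of which 177 rose and 356 fell at least 2-fold. In 43.6% of genes the groups did not overlap, against 10% by chance. *FKBP1A*, the rapamycin-binding protein, was not called (-0.08 ± 0.033), and the calls of *MTOR* (0.17 ± 0.042) and *ACTB* (0.21 ± 0.029) were lost against a 1.2-fold change.

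The groups were also compared through their shifts from the same DMSO libraries. Full-length and untriggered split Csy4 had 1985 genes higher in both and 1969 lower in both, where independent calls would give 606 and 609, with 125 opposite. Full-length and triggered split Csy4 shared 2259 and 2242 (656 and 675 if independent), with 79 opposite, and the split groups shared 2134 and 2035 (423 and 396), with 0 opposite. Full-length Csy4 and rapamycin shared 1299 higher and 1435 lower genes (706 and 691 if independent), with 939 opposite. Across 15185 genes, which are not independent replicates, Pearson's r of the log2 fold changes was 0.74, 0.77, 0.86 and 0.38 in that order. Log2 fold changes had the same sign in 76.5, 79.6, 85.4 and 61.4% of these genes. Simulated groups that shared only the DMSO libraries, with no change of their own, gave an r of 0.49 and a same-sign share of 66.2%. Full-length Csy4 and rapamycin lay below both values. Changes that differ between groups lower r and are absent from the simulation, so this does not speak against a shared part. For the other 3 pairs part of the excess may come from the shared controls. The covariances were 0.123, 0.136, 0.105 and 0.0704, against 0.0137 in the 20 simulations, so that of full-length Csy4 and rapamycin was also above the simulated value.

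The difference between the effects of grazoprevir with and without split Csy4 was tested as an interaction. Cells without split Csy4 were also untransfected, so an influence of transfection on the response and one of split Csy4 cannot be told apart. *DNAH17* had a log2 fold change of 1.63 with split Csy4 and of -0.40 without it, the latter not called, an interaction of 2.03 ± 0.31. *TP53INP1* had an interaction of 0.68 ± 0.1 and *CDKN1A* of 0.46 ± 0.092, both with a rise in transfected cells. *RPS29* had an interaction of -0.41 ± 0.067 and *RPLP1* of -0.27 ± 0.049, both with a rise in untransfected cells. edgeR called 63 genes (0.351%), 32 with a positive and 31 with a negative interaction, 1659 genes had an unadjusted p below 0.05, and 14 of the 31 belonged to the ribosomal protein list. Of the 32, 14 were called higher in the split arm, and of the 31, 12 were called higher with grazoprevir alone. The count moved to 14 without SplitCsy4_Grazoprevir replicate 1, 25 without SplitCsy4_Grazoprevir replicate 2, 28 without SplitCsy4_DMSO replicate 2, 16 without SplitCsy4_DMSO replicate 3, 24, 37 and 38 without DMSO replicates 1, 2 and 3, 141 without Grazoprevir replicate 1 and 27 without Grazoprevir replicate 2. The calls of *TP53INP1*, *CDKN1A*, *RPS29* and *RPLP1* were lost against a 1.2-fold change.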

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

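The tests of single-library and of length and GC effects below were planned before their results were seen, and the length and GC correction itself was chosen after the data were examined. The effect of grazoprevir differed between split Csy4 and untransfected cells in 63 genes by the interaction test, which cannot separate split Csy4 from its transfection. Interactions on the log2 scale were positive for *DNAH17* (2.03), *DUSP8* (1.08), *NRAV* (0.90), *ZNF79* (0.71), *ANKRD1* (0.68), *TP53INP1* (0.68), *CDKN1A* (0.46), *CREB5* (0.40), *BTG2* (0.35), *CENPE* (0.26), *MDM2* (0.24) and *CENPF* (0.18). They were negative for *C12orf57* (-0.67), *RPS29* (-0.41), *MYDGF* (-0.38), *ENY2* (-0.37), *SSR4* (-0.37), *RPS21* (-0.33), *NDUFAB1* (-0.32), *DCTPP1* (-0.32), *RPLP1* (-0.27), *RPLP2* (-0.26) and *PDIA3* (-0.21). The call of *DNAH17* held in the 21 alternatives that gave it an adjusted p, and among those that did so for them, the calls of *DUSP8*, *TP53INP1*, *CDKN1A*, *CREB5*, *RPS29* and *RPLP1* ended only against a 1.2-fold change. DESeq2 gave no adjusted p for the interaction of *DNAH17*, *DUSP8*, *TP53INP1*, *CDKN1A* and *CREB5*. *CENPE* also lost its call with the length and GC correction. For the other 15 genes the call ended without at least 1 library, and each of the 12 libraries ended at least 1 of these calls (highest adjusted p over the alternatives 1). The count of 63 moved to 14, 25, 28, 16, 24, 37, 38, 141 and 27 without SplitCsy4_Grazoprevir replicates 1 and 2, SplitCsy4_DMSO replicates 2 and 3, DMSO replicates 1, 2 and 3, and Grazoprevir replicates 1 and 2. In a fit of these 4 groups alone the interaction called 72 genes. Of 100 regroupings of grazoprevir within each arm, drawn from those possible with the real one among them, only the real one called as many. The highest other called 45. The share of 0.01 is the smallest that 100 regroupings allow, and single libraries moved the count of 63 as given above. The regroupings argue against chance but do not exclude it.

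With grazoprevir alone 10 of 79 ribosomal protein genes were called higher, and 14 of the 31 negative interactions were in this list, which was called with the preset correlation and not with an estimated one (adjusted p = 0.147). The shift was not due to Grazoprevir replicate 1, since without it the list's median log2 fold change kept 103% of its size (0.08) and 14 members were called. The calls did depend on other libraries: without DMSO replicate 1 the whole comparison called only 3 genes. A trend with transcript length stays open: log2 fold changes of grazoprevir fell with length across 14998 genes (Spearman -0.24, genes not being independent replicates). The longest annotated transcripts of ribosomal protein genes were short (median 1857 against 3427 bases). These need not be the forms expressed, so the correction may not match the lengths sequenced. After each library's trend was removed the median kept 59.1% of its size (from 0.078 to 0.046) and the called members went from 10 to 4, so a length trend and a response to the drug cannot be told apart here.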

How the results depend on the processing

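Library-size scaling and the length and GC correction were chosen after the data were seen. Of the values of named genes under the alternatives, 13237 stayed on the same side of the threshold, 932 lost their call and 12 gained one. Among values called in the main fit or under the alternative, 0 reversed direction. The direction of values called in neither was not counted. The 4 differences in distance from DMSO kept their direction, but with mean CPM minimums of 50 and 1 those of full-length Csy4 moved by more than the spread between replicates: to 0.112 and 0.131 for full-length less untriggered split Csy4, 0.0981 and 0.113 less triggered split Csy4, and 0.0704 and 0.0986 less rapamycin. Triggered less untriggered split Csy4 ran from 0.0139 to 0.0184 over the alternatives. Numbers of called genes, and of called lists, stayed within 1.5 times their values except as follows, and where no construction is named the cause was not tested. Against a 1.2-fold change, a stricter test by construction, edgeR called 3647 genes for full-length, 812 for untriggered and 1145 for triggered split Csy4 against DMSO, and 1406 for rapamycin. Grazoprevir alone had 0 (1526 at an unadjusted p below 0.05 without that threshold, 99 with DESeq2). Triggered against untriggered split Csy4 had 6, triggered split Csy4 against grazoprevir 1160, full-length against untriggered 863 and against triggered split Csy4 647, and the interaction 1. For grazoprevir against DMSO the count of 36 became 66 with replicate number as a block, although not every same-number pair of DMSO and grazoprevir libraries correlated above 0.1 (0.23, 0.18 and 0.02, against -0.22 to 0.1 for unlike numbers), and 3 of 30 such pairs over all groups did. It became 7 with only the groups compared, 99 with DESeq2, which gave adjusted p to 1970 genes, and 18 with the length and GC correction (39 in the same genes uncorrected). DESeq2 called 123 interactions, with adjusted p for 2734 genes. Triggered against untriggered split Csy4 had 59 calls with the correction. Leaving out 1 library lowers the number of samples: counts ran from 3 (without DMSO replicate 1) to 112 (without Grazoprevir replicate 1) for grazoprevir, from 22 (without SplitCsy4_DMSO replicate 2) to 29 (without SplitCsy4_DMSO replicate 1) for triggered against untriggered, and from 14 (without SplitCsy4_Grazoprevir replicate 1) to 141 (without Grazoprevir replicate 1) for the interaction. They ran from 7633 to 7737 for full-length, 4262 to 4521 for untriggered and 4703 to 4975 for triggered split Csy4 against DMSO, and 5034 to 5321 for rapamycin. With an estimated correlation the called lists became 0 for untriggered and 2 for triggered split Csy4 against DMSO, 0 for grazoprevir, 10 for rapamycin, 5 for triggered against untriggered split Csy4, 2 for triggered split Csy4 against grazoprevir, and 6 and 7 for full-length against untriggered and triggered split Csy4. With fry, which asks only whether a list moves one way, they became 20 for full-length and 21 for triggered split Csy4 against DMSO, 1 for grazoprevir and 6 for triggered against untriggered split Csy4. No block could be run for rapamycin, whose columns carry no number. Changes near 1.2-fold were missed in most genes in counts simulated at this depth, with 36% recovered. Few genes were changed in that simulation, so this share does not carry over to comparisons with many calls.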

Other observations

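The zinc finger family and the tests of normalization and of transfection were chosen after the results were seen. Genes named ZNF, most of which encode zinc finger transcription factors, were higher with full-length Csy4. Of 491 tested, 233 rose and 17 fell against untriggered split Csy4, at a median of 0.26, while 12.1% of all other genes rose against 47.5% of the family. Camera with an estimated correlation gave an adjusted p of 4.82e-08, here adjusted over the comparisons and not over lists. This p comes from the libraries that prompted the choice, so it is no independent support. Against triggered split Csy4 195 rose and 20 fell, at a median of 0.22, and against DMSO 273 rose and 40 fell, at a median of 0.33. With untriggered split Csy4 101 rose and 43 fell against DMSO (median 0.06), with triggered split Csy4 135 and 38 (median 0.12), with rapamycin 133 and 27 (median 0.11), and with grazoprevir alone 0 and 1 (median -0.01). Against untriggered split Csy4 the direction was the same with median-of-ratios factors (0.26) and library-size scaling (0.32).

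The p53 targets were higher with full-length than with untriggered split Csy4, at a list median of 1.00 (quartiles 0.52 and 1.24). The tables argue against normalization as the cause, since the smaller of the medians under library-size scaling and median-of-ratios factors was 1.005. They argue against depth too, with a median of 0.998 and 21 members higher after every library was thinned to 12362101 counts. Untriggered split Csy4 reached 15% of the list's median with full-length Csy4 against DMSO, but this restates the difference and decides nothing about transfection. The amount of construct and the share of cells transfected were not measured, so a difference in transfection and an effect of the enzyme's activity cannot be told apart here.

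A candidate explanation for genes lower with full-length than with untriggered split Csy4 is direct cutting at hairpins like the Csy4 site. The exact site was found in 0 genes among 14998 with a searched transcript, which are 83.5% of those tested. In 97 genes with the loop on a stem of 5 Watson-Crick pairs the median log2 fold change was -0.057, at percentile 6.99 of 10000 sets matched on expression and length (95% of sets from -0.067 to 0.037), and 0.7% of falling genes held such a hairpin against 0.65% of all. With wobble pairs allowed, in 514 genes, the median of -0.045 lay below the range of 95% of matched sets (-0.044 to -0.00084). This was percentile 2.02, under the limit of 2.5 set for the first form, and 4.1% of falling genes held one against 3.4% of all. In 383 genes with the loop and a sequence close to the exact site, paired or not, the median lay at percentile 24.4 (2.8% against 2.6%). An effect on genes with a hairpin stays open, as do introns, which were not searched. Transcript length or GC content is argued against as the whole cause, since 86.6% of falling calls (2300 of 2655) remained after its correction.

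Splits of the 6 libraries of a comparison into other groups of 3 number 10 with the real one, so a share under 0.05 cannot be reached. The real split and the highest other called 8578 and 0 genes for full-length, 5421 and 0 for untriggered and 6098 and 0 for triggered split Csy4 against DMSO, 6306 and 0 for rapamycin, and 7 and 1 for grazoprevir. They called 5333 and 0 for triggered split Csy4 against grazoprevir, and 5132 and 0, and 4403 and 0, for full-length against untriggered and triggered split Csy4. For each of these, 1 of the 10 splits, the real one, called as many genes. For triggered against untriggered split Csy4 2 of 10 did: the real split called 48 genes, and the split of SplitCsy4_DMSO replicate 1 with SplitCsy4_Grazoprevir replicates 1 and 2 from the other 3 libraries called 58.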
